A study of Rattus norvegicus with 13 samples.

How the data were processed

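The values were analysed as deposited. Per the labels, total RNA was extracted with Trizol, made into biotin-labelled cRNA and hybridized to single-colour Affymetrix rat arrays, and the authors computed the deposited expression values by RMA. The version of RMA and the arrays normalized together are not given in the sources used here. The log2 scale was inferred from the range of the deposited values (2.94 to 14.69), and nothing was transformed or normalized again before the fits. Of 31099 probe sets, 57 controls were left out, 20826 named a single gene, 436 named several and 9780 named none. Symbols were brought up to date by Entrez identifier for 20758 probe sets, by accession for 2, and kept for 66. Each of the 14217 genes was represented by the probe set with the highest mean over the 13 arrays, a choice that affects the 4525 genes with several probe sets.

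Differences were tested with limma 3.58.1 in R 4.3.3, on group means with moderated statistics, without a trend and not robust, and adjusted by the method of Benjamini and Hochberg over all genes. A gene was called at adjusted p under 0.05. A fit of 9 arrays held the lines grown alone and in co-culture, and a fit of 11 arrays held the tumours and the lines grown alone. Tests were two-sided, apart from Fisher's exact test for list members above both lines, which was one-sided. Genes on the same side of both lines were called in both tumour comparisons with the same sign. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 21 lists. Statmod 1.5.0 served the replicate block. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

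The groups, comparisons, gene lists, main settings and alternatives were fixed before the data were examined. The alternatives were a single fit of all 13 arrays, a further quantile normalization, centring on the median, leaving out the lowest expressed part of the genes, the mean of the probe sets of a gene, every probe set on its own, a trend with robust moderation, a 2-fold limit, a limit of 0.01 on the adjusted p, each array left out, the replicate number as a block, array weights, a test of only the groups compared, limits of 4-fold and 16-fold for the position between the lines, and an estimated correlation within lists. Added after the data were seen were tumours 1 and 4 left out, tumour 2 as the only tumour, pairs of fibroblastic arrays left out, and the comparisons with both lines and with a mixture in co-culture.

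The lists, with genes measured of genes listed, were cholangiocyte and epithelial junction genes (28 of 33), mucins and secreted epithelial products (17 of 20), myofibroblast and mesenchymal genes (28 of 29), fibrillar collagens and interstitial matrix (29 of 30), basement membrane (19 of 21), matrix proteases and inhibitors (25 of 27), growth factor ligands (31 of 34), growth factor receptors (25 of 29), TGF-beta targets (20 of 22), cytokines and chemokines (31 of 32), interferon response (24 of 25), proliferation (37 of 39), hypoxia and glycolysis (27 of 29), cholesterol biosynthesis (19 of 24), immediate early and heat shock genes (22 of 26), unfolded protein response and amino acid stress (24 of 24), macrophage and antigen presenting cells (26 of 27), T, B and NK cells (21 of 25), endothelial cells (19 of 22), hepatocytes (23 of 25), and erythrocytes and mast cells (10 of 13). Cxcl5 and Cxcl6 resolve to the same rat gene. An error in matching was corrected after values had been seen: Tf had matched F3 and Ephb2 had matched Ephb1 through synonyms. Both are now unmatched, and every value given here was computed after the correction.

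The rule for naming genes was set before the data were examined. For each comparison of replicated groups it takes the 8 largest positive and 8 largest negative log2 differences among called genes whose arrays do not overlap, and for co-culture 10 and 10. For each called list it takes the 3 called members with the largest difference in the direction of the list. It always includes Acta2, Vim, Krt19, Krt7, Cdh1, Postn, Tnc, Fn1, Col1a1, Muc1, Erbb2, Met, Msln and Mki67. Position between the lines was computed on the linear scale for genes called and at least 8-fold apart, each array grown alone against the other arrays of its line. Percentiles come from 10000 random lists matched on expression.

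The method was tried on simulated data with 200 genes changed, 100 by a log2 difference of 1 and 100 by 2. Of these it recovered 42 and 83 for the lines (2 false calls), 57 and 87 for tumours against the epithelial line (9 false), 69 and 93 for tumours against the fibroblastic line (17 false), 17 and 55 for the epithelial co-culture (2 false), 6 and 61 for the fibroblastic co-culture (1 false), and 0 and 0 for the difference in response (0 false). In co-culture most changes of 1 are therefore missed, as are changes of either size in the difference in response, and a gene not called there is not shown to be unchanged. A shifted list was found (adjusted p = 2.41e-24) with 0 other lists called. A simulated share of 30% was estimated at 29.6%. The mixture comparison recovered 160 of 200 genes with 0 false when given the true share and mixtures of the same means. It was not tried with estimated shares, so this gives no limit on false calls in the measured arrays.

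Left out were probe sets naming several genes or none, probe level data, pathway databases, and comparison with human tumours, none of which were analysed here. The plating density of the arrayed co-cultures, the separation of the cells and the scan dates are not given in the sources used here.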

Results

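Expression was measured in rat cholangiocarcinoma, a cancer of the bile ducts, and in cell lines derived from it. The tumours grew in the livers of Fischer 344 rats from BDEsp cells, a spontaneously transformed bile duct epithelial line, and 4 of them were snap-frozen and profiled. A cholangiocarcinoma cell line (clone H10, called the epithelial line here) and a fibroblastic line positive for alpha smooth muscle actin (clone E4) were derived from such tumours and grown in gels of rat tail type I collagen. The epithelial line grown alone gave 3 arrays and the fibroblastic line grown alone gave 4. A single array was labelled as epithelial cells from co-culture with the fibroblastic line, and 1 as fibroblastic cells from co-culture with the epithelial line. Each of the 13 arrays held 31099 probe sets, 57 of them controls, and the 20826 that name a single gene measured 14217 genes. The deposited values ran from 2.94 to 14.69 on the log2 scale, with array medians between 6.14 and 6.25. Arrays have no counting depth, so the number of arrays limits the precision of every value. Whether the cultures of a line were independent is not given in the sources used here, so the p-values measure only the spread between these arrays. The lone co-culture arrays were assumed to vary like the replicated groups.

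The comparison of the lines grown alone asked how far the cancer cells and the fibroblastic cells differ without contact. They differed most in the genes that define an epithelium and a connective tissue. Krt19, a keratin of bile duct epithelium, stood at 14.07 ± 0.17 (SD, n = 3) in the epithelial line and 4.18 ± 0.12 (SD, n = 4) in the fibroblastic line, a log2 difference of 9.89 (SE 0.15, limma adjusted p = 1.97e-08). Postn, which encodes the matrix protein periostin, was the mirror image at 3.87 ± 0.23 (SD, n = 3) and 14.04 ± 0.06 (SD, n = 4), a difference of -10.18 (SE 0.15, adjusted p = 1.97e-08). In all, 2967 genes were higher in the epithelial line and 2357 lower, 5324 of 14217, and 3310 of these differed at least 2-fold. The median difference over all genes was 0.11, small beside the differences given here.

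Among the genes furthest above the fibroblastic line were the keratin Krt18 (9.28), the tetraspanin Tspan8 (9.05) and the adherens junction cadherin Cdh1 (8.68), as log2 differences. With them came the calcium-binding protein Ocm (8.54), the adhesion molecule Epcam (8.44), the surface glycoprotein Cd24 (8.27) and the galectin Lgals4 (8.06). The other direction was led by the type I collagen chain Col1a2 (-10.01), the calcification inhibitor Mgp (-9.37), and fibronectin Fn1 (-9.27). Next were the bone morphogenetic protein antagonist Grem1 (-9.19), Nrep (-9.11), the nidogen Nid1 (-8.81) and Col5a2 (-8.75). Every array of 1 line lay apart from every array of the other for these genes. The smooth muscle actin gene Acta2, the label's marker of the fibroblastic line, was lower in the epithelial line by a log2 difference of -4.03 (SE 0.74, adjusted p = 0.00365), with a wide spread among the fibroblastic arrays (10.94 ± 1.39, SD, n = 4). Vim (-6.04), Tnc (-7.84) and Col1a1 (-7.98) were lower in the epithelial line too. The epithelial line was higher in Krt7 (6.70, SE 1.00, adjusted p = 0.00131), Msln, which encodes the surface antigen mesothelin (6.60), the mucin Muc1 (3.49) and the receptor kinase Erbb2 (2.01). The hepatocyte growth factor receptor Met differed by 0.84 (SE 0.25, adjusted p = 0.0318), a call that ended without epithelial array 1 or 3 or fibroblastic array 2 or 4, with an adjusted p of up to 0.105. The proliferation marker Mki67 differed by 1.01 and was not called (adjusted p = 0.171).

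**Figure D1:**
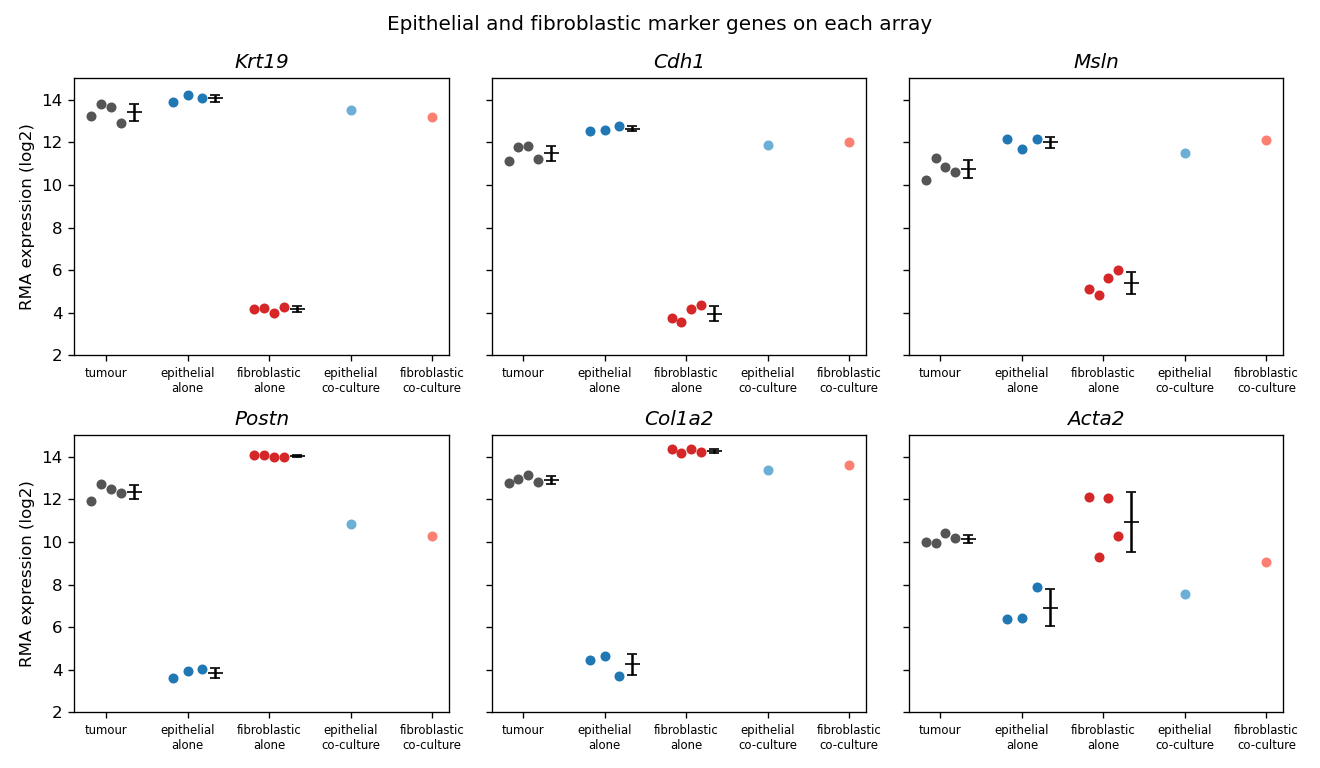
RMA expression (log2, vertical axis) of the epithelial markers Krt19, Cdh1 and Msln and of the fibroblastic markers Postn, Col1a2 and Acta2 in the 5 groups of arrays (horizontal axis); each point is an array and the bars beside the replicated groups give the mean and SD. Krt19 stands at 14.07 in the epithelial line and 4.18 in the fibroblastic line, and both co-culture arrays hold Krt19, Cdh1, Msln, Postn and Col1a2 well above the line that lacks them, while Acta2 in the epithelial co-culture array lies within the range of the epithelial line.

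Of 21 gene lists, camera called 10 between the lines, 4 higher and 6 lower in the epithelial line. Of 28 cholangiocyte and epithelial junction genes measured, 26 were higher and 0 lower (26 and 0 adjusted over the list alone), with a median log2 difference of 5.42 (adjusted p = 1.47e-18, and adjusted p = 0.0276 with an estimated correlation). Of 17 mucins and secreted epithelial products, 9 were higher and 1 lower (11 and 1 adjusted over the list alone), led by the vesicle protein Mal2 (8.03) and the immunoglobulin transporter Pigr (7.04), at adjusted p = 0.00567 and adjusted p = 0.488 with an estimated correlation. Cell cycle genes of the proliferation list were higher in 18 of 37, such as Cdkn3 (2.98), Pttg1 (2.31) and Ube2c (2.25), and 0 were lower, the same counts as adjusted over the list alone (median 1.42). That list was called at adjusted p = 8.05e-05, and at adjusted p = 0.594 with an estimated correlation. Its mean in fibroblastic array 3 (9.504) exceeded that in epithelial array 2 (9.201), while fibroblastic array 2 stood at 7.333. Of 19 genes of cholesterol biosynthesis, 17 were higher and 0 lower (17 and 0 adjusted over the list alone), with Idi1 (3.80), Tm7sf2 (3.19) and Fdps (2.80) in front, at adjusted p = 2.75e-06 and adjusted p = 0.488 with an estimated correlation. The mean of this list was lower in fibroblastic arrays 2 and 4 (7.82 and 7.81) than in arrays 1 and 3 (9.03 and 8.82), and the actin measure of RNA quality differed between the same arrays (2.65 and 2.01 against 1.72 and 1.05). The GAPDH measure did not separate them (0.270 and 0.147 against 0.151 and -0.038).

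Lower in the epithelial line were 23 of 28 myofibroblast and mesenchymal genes (23 adjusted over the list alone), among them the cadherin Cdh11 (-8.12, with 1 of its 3 probe sets of opposite sign), the tropomyosin Tpm2 (-7.98) and the contractile protein gene Tagln (-7.18). Their median was -4.27 (adjusted p = 1.15e-13, and adjusted p = 0.00713 with an estimated correlation). Fibrillar collagens and interstitial matrix were lower in 25 of 29 and higher in 1 (26 and 1 adjusted over the list alone), with a median of -6.11 (adjusted p = 2.45e-19, and adjusted p = 0.0104 with an estimated correlation). Of 20 TGF-beta target genes, 13 were lower and 0 higher (14 and 0 adjusted over the list alone), at adjusted p = 4.84e-07 and adjusted p = 0.0147 with an estimated correlation. Basement membrane genes were lower in 9 of 19 and higher in 4 (9 and 4 adjusted over the list alone), with Col4a5 (-6.22) and the laminin chain Lama4 (-5.58) lowest, at adjusted p = 0.00427 and adjusted p = 0.154 with an estimated correlation. Of 25 matrix proteases and inhibitors, 14 were lower and 1 higher (15 and 1 adjusted over the list alone), led by the gelatinase Mmp2 (-7.50, with 1 of its 2 probe sets of opposite sign), Serpine2 (-7.40) and Adamts1 (-6.38), at adjusted p = 3.19e-05 and adjusted p = 0.154 with an estimated correlation. Growth factor ligands were lower in 13 of 31 and higher in 5 (14 and 5 adjusted over the list alone), with the activin subunit Inhba (-7.44), the lymphatic growth factor Vegfc (-5.66) and Tgfb3 (-4.28) in front, at adjusted p = 0.0104 and adjusted p = 0.231 with an estimated correlation.

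The remaining lists were not called between the lines. Their adjusted p-values were 0.0744 for cytokines and chemokines and for hypoxia and glycolysis, and 0.103 for the unfolded protein response and amino acid stress. They were 0.229 for growth factor receptors, 0.258 for interferon response and for hepatocyte markers and 0.303 for T, B and NK cell markers. Others were 0.627 for erythrocyte and mast cell markers, 0.769 for endothelial cell markers and 0.963 for macrophage and antigen presenting cell markers. For immediate early and heat shock genes (adjusted p = 0.751) the median was 0.18 while the mean was -0.30 and the test pointed down. Leaving out 1 array brought new calls: cytokines without epithelial array 1 (0.0261) or 2 (0.0275) or fibroblastic array 4 (0.0400), hypoxia without epithelial array 1 (0.0491) or 3 (0.0116), and the unfolded protein response without epithelial array 1 (0.0358). With the lowest expressed genes left out cytokines were called (0.00846) and ligands were not (0.0504), and without fibroblastic arrays 2 and 4 the unfolded protein response was called (0.0312). Among the named genes, the call of Pttg1 ended without epithelial array 1 or 3 or fibroblastic array 4 (adjusted p up to 0.0791), and that of Ube2c without any of the 3 epithelial arrays or fibroblastic arrays 1, 2 or 4 (up to 0.116).

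The tumours were then compared with the epithelial line, which shows what the tissue holds beyond its cancer cells as grown in culture. Genes of the matrix, of antigen presentation and of the liver were among those furthest above the epithelial line. Mgp stood at 13.59 ± 0.32 (SD, n = 4) against 4.44 ± 0.39 (SD, n = 3), a log2 difference of 9.15 (SE 0.25, adjusted p = 1.99e-09), and Col1a2 (8.65), Postn (8.49) and the proteoglycans Lum (8.20) and Dcn (7.88) followed. Selenop, a plasma selenium carrier made mainly by the liver, differed by 9.20, and the antigen presentation genes Cd74 (8.19) and RT1-Da (7.97) stood out too. Lower in the tumours were the stress-induced cytokine Gdf15 (-4.45) and the epidermal growth factor receptor ligands Areg (-4.38) and Ereg (-3.92). So were the neutrophil chemokine Cxcl1 (-4.11), Mal (-4.08), the inducible cyclooxygenase Ptgs2 (-3.97), the actin regulator Wasf2 (-3.65) and Qrich1 (-3.47). All these genes separated every tumour from every epithelial array.

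Of 14217 genes, 2685 were higher and 4722 lower in the tumours than in the epithelial line, 7407 called, of which 3465 differed at least 2-fold. The median over all genes was -0.17, and with each array centred on its median the split turned to 3751 higher and 3431 lower, so the balance of directions rests on the scaling. With the lowest expressed genes left out it was 1315 and 4316. The groups also differed in a sign of RNA quality, the log2 difference between the 3' and 5' actin probe sets, which was 0.606 to 0.752 in the tumours, 0.857 to 1.47 in the epithelial line and 1.05 to 2.65 in the fibroblastic line. How many of the calls follow it was not tested. Fn1 (7.88), Col1a1 (6.04), Tnc (5.76), Vim (4.52), Acta2 (3.23) and Met (1.27) were higher in the tumours, and Erbb2 (-1.78), Msln (-1.26) and Cdh1 (-1.16, with 1 of its 2 probe sets of opposite sign) lower. Krt19 was lower by a log2 difference of -0.66 (SE 0.20, adjusted p = 0.0192), a call that ended without tumour 1 or epithelial array 2 (up to 0.0690). Differences of -1.11 for Krt7 (adjusted p = 0.308), 0.52 for Muc1 (0.238) and -1.22 for Mki67 (0.0565) were not called.

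Camera called 16 lists between tumours and epithelial line, 13 higher and 3 lower in the tumours. All 26 macrophage and antigen presenting cell markers measured were higher (26 adjusted over the list alone), with a median of 4.97 (adjusted p = 1.23e-27, and adjusted p = 0.00422 with an estimated correlation) and with RT1-Bb (7.73) beside the genes above. T, B and NK cell markers were higher in 17 of 21 (18 adjusted over the list alone), such as the cytotoxic T cell gene Cd8a (5.20), Cd3g (3.16) and the granzyme Gzmb (3.08), at adjusted p = 5.60e-11 and adjusted p = 0.0188 with an estimated correlation. Endothelial markers were higher in 15 of 19 and lower in 1, with Lyve1 (3.48) and Emcn (3.21), at adjusted p = 1.36e-09 and adjusted p = 0.0343 with an estimated correlation. Collagens and interstitial matrix were higher in 25 of 29 (26 adjusted over the list alone; median 4.65; adjusted p = 1.23e-22, and adjusted p = 0.00422 with an estimated correlation). Myofibroblast and mesenchymal genes were higher in 23 of 28 and lower in 3, with Tagln (5.72), Tpm2 (4.70) and the transcription factor Zeb2 (4.59), at adjusted p = 2.14e-09 and adjusted p = 0.00422 with an estimated correlation. Proteases and their inhibitors were higher in 18 of 25 and lower in 1, with the macrophage elastase Mmp12 (7.70), the cathepsin Ctss (6.11) and Serpine2 (5.83), at adjusted p = 2.08e-08 and adjusted p = 0.0343 with an estimated correlation.

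Hepatocyte markers were higher in 22 of 23, with albumin Alb at 7.62 (SE 1.39) and the fibrinogen chains Fgg (7.28) and Fga (7.05), but they were far from uniform among the tumours. Alb stood at 7.50 in tumour 2 and at 13.94 to 14.51 in tumours 1, 3 and 4. The list was called at adjusted p = 1.65e-07, and at adjusted p = 0.346 with an estimated correlation. With tumours 1 and 4 left out, a choice made after seeing these values, 4549 genes were called between tumours and epithelial line, and with tumour 2 as the only tumour 1958.

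**Figure D2:**
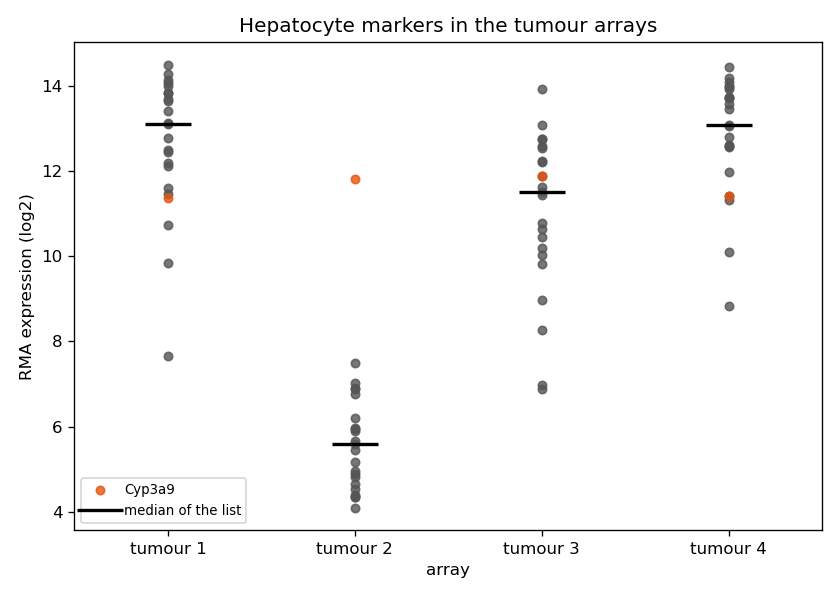
RMA expression (log2, vertical axis) of 23 hepatocyte markers in each of the 4 tumours (horizontal axis); each point is a gene, the black bar is the median of the list, and Cyp3a9 is orange. Tumour 2 lies below the others in 22 of the 23 genes, Cyp3a9 being the exception.

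Mucins and secreted products were higher in the tumours in 6 of 17 and lower in 1, led by osteopontin Spp1 (7.49), the plasma ferroxidase Cp (5.19) and Muc13 (3.50), at adjusted p = 0.0108 and adjusted p = 0.291 with an estimated correlation. Interferon response genes were higher in 13 of 24, such as Ifit2 (2.92), Ifit3 (2.71) and Irf7 (2.07), at adjusted p = 7.63e-05 and adjusted p = 0.291 with an estimated correlation. Tumour 2 was the highest tumour in 19 of the 24, with a median of 1.20 above the mean of the others. Erythrocyte and mast cell markers were higher in 6 of 10, with the globin Hbb (3.71), Mcpt1 (1.43) and Cpa3 (1.23), at adjusted p = 0.000710 and adjusted p = 0.186 with an estimated correlation. Growth factor receptors were higher in 13 of 25 and lower in 6, with Cxcr4 (4.06), Kdr (3.05) and Pdgfra (2.83), at adjusted p = 0.00889 and adjusted p = 0.0949 with an estimated correlation. TGF-beta targets were higher in 8 of 20 and lower in 5, with Tgfbi (6.13), at adjusted p = 0.0394 and adjusted p = 0.114 with an estimated correlation. Genes of the unfolded protein response and amino acid stress list were higher in 9 of 24 and lower in 5 (10 and 5 adjusted over the list alone), with Calr (1.67) and Hspa5 (1.59) ahead of Sdf2l1, at adjusted p = 0.0471 and adjusted p = 0.459 with an estimated correlation. Lower in the tumours were 14 of 28 cholangiocyte genes, with Tjp1 (-1.62), Jup (-1.42) and St14 (-1.34), at adjusted p = 0.0230 and adjusted p = 0.503 with an estimated correlation. Cholesterol genes were lower in 14 of 19 (16 adjusted over the list alone), with Sqle (-2.62), Tm7sf2 (-2.32) and Mvd (-2.29), at adjusted p = 0.000489 and adjusted p = 0.402 with an estimated correlation. Proliferation genes were lower in 13 of 37 (10 adjusted over the list alone), with Mcm4 (-1.92), Cdkn3 (-1.65) and Mcm5 (-1.48), at adjusted p = 0.00655 and adjusted p = 0.605 with an estimated correlation.

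Several of these calls rested on single arrays. The cholangiocyte list lost its call without tumour 4 (0.0539) or epithelial array 2 (0.0912), and TGF-beta targets without tumour 2 (0.0517) or epithelial array 2 (0.0513) or 3 (0.0626). The unfolded protein response lost it without tumour 1, 2 or 3, epithelial array 2 or 3, or fibroblastic array 2 or 3 (0.0517 to 0.136), and Cdkn3 without any tumour, any epithelial array or fibroblastic array 1 (up to 0.137). Cytokines and chemokines were not called (adjusted p = 0.0702, with a median of -0.05, a mean of 0.25 and a test pointing up). They were called without epithelial array 3 (0.0164), with the lowest expressed genes left out (0.0147) and with tumour 2 as the only tumour (0.0315). Growth factor ligands (0.0914) were called higher with the lowest expressed genes left out (0.00462). At that setting the calls of the cholangiocyte list (0.215) and of proliferation (0.108) ended, and that of TGF-beta targets ended with the mean of the probe sets of a gene (0.0559). The cholangiocyte list and the unfolded protein response also lost their calls with tumours 1 and 4 left out (0.206 and 0.0666) and with tumour 2 as the only tumour (0.299 and 0.116). Basement membrane genes (0.188), hypoxia and glycolysis (0.550) and immediate early genes (0.617) were not called.

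Against the fibroblastic line, the genes furthest higher in the tumours were mostly epithelial genes. Krt19 stood at 13.40 ± 0.41 (SD, n = 4) against 4.18 ± 0.12 (SD, n = 4), a log2 difference of 9.23 (SE 0.19, adjusted p = 2.63e-10). Tspan8 (9.24), Epcam (8.65), Krt18 (8.53), Lypd8 (8.49), Lgals4 (8.31), Pigr (8.23) and the antibacterial lectin Reg3g (8.07) completed the genes with the highest differences. Which cells of the tumours express them was not tested. Lower in the tumours were the carboxypeptidase Cpe (-7.05), Grem1 (-6.50), the guidance molecule Slit2 (-6.05), the transcription factor Foxp2 (-5.75), Col8a2 (-5.56), Cdhr1 (-5.50), the scaffold protein Akap12 (-5.48) and C1qtnf3 (-5.46). Of 14217 genes, 3888 were higher and 4764 lower, 8652 called, 4343 of them at least 2-fold. With each array centred on its median the split was 5095 higher and 3821 lower, so its balance too rests on the scaling. With the lowest expressed genes left out it was 1837 and 4117.

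Cdh1 (7.52), Krt7 (5.59), Msln (5.34), Muc1 (4.01) and Met (2.12) were higher in the tumours than in the fibroblastic line. Tnc (-2.08), Col1a1 (-1.94), Postn (-1.69), Vim (-1.52) and Fn1 (-1.39) were lower. Acta2 differed by -0.80 (SE 0.60, adjusted p = 0.267), Erbb2 by 0.24 (0.362) and Mki67 by -0.21 (0.703), and these were not called. With tumour 2 as the only tumour, 3912 genes were called.

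Camera called 15 lists between tumours and fibroblastic line, 11 higher and 4 lower in the tumours. Cholangiocyte genes were higher in 24 of 28 and lower in 1, with a median of 4.97 (adjusted p = 6.03e-15, and adjusted p = 0.0727 with an estimated correlation). Mucins and secreted products were higher in 14 of 17, with Mal2 (7.76) and Agr2 (7.16), at adjusted p = 1.21e-06 and adjusted p = 0.0607 with an estimated correlation. All 26 macrophage markers were higher, with Cd74 (7.71), RT1-Da (7.68) and RT1-Bb (7.54), at adjusted p = 8.80e-21 and adjusted p = 0.0256 with an estimated correlation. T, B and NK cell markers were higher in 20 of 21, with Cd8a (5.64), Cd69 (4.90) and Gzmb (3.23), at adjusted p = 8.12e-10 and adjusted p = 0.0261 with an estimated correlation. Endothelial markers were higher in 14 of 19, with Emcn (3.28), Kdr (3.00) and Lyve1 (2.88), at adjusted p = 2.52e-07 and adjusted p = 0.0607 with an estimated correlation. Hepatocyte markers were higher in 23 of 23, with Alb (7.47), Fgg (7.29) and Fga (7.13), at adjusted p = 1.05e-06 and adjusted p = 0.381 with an estimated correlation. Erythrocyte and mast cell markers were higher in 6 of 10, with Hbb (3.84), Mcpt1 (1.60) and Cpa3 (1.28), at adjusted p = 0.00133 and adjusted p = 0.198 with an estimated correlation.

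Cytokines and chemokines were higher in the tumours than in the fibroblastic line in 20 of 31 and lower in 4, with the alarmin Il33 (7.11), Cxcl6 (6.25) and Cxcl11 (4.87), at adjusted p = 1.22e-05 and adjusted p = 0.191 with an estimated correlation. Interferon response genes were higher in 21 of 24 (21 higher and 1 lower adjusted over the list alone), with the immunoproteasome subunit Psmb8 (4.20), Gbp2 (3.29) and Cxcl10 (3.14), at adjusted p = 1.33e-05 and adjusted p = 0.234 with an estimated correlation. Hypoxia and glycolysis genes were higher in 12 of 27 and lower in 4 (12 and 3 adjusted over the list alone), with Ndrg1 (4.65), the oxygen sensor Egln3 (3.33) and Ddit4 (2.48), at adjusted p = 0.0265 and adjusted p = 0.525 with an estimated correlation. Cholesterol genes were higher in 10 of 19 and lower in 2, with Idi1 (2.12), Dhcr7 (1.54) and Sc5d (1.41), at adjusted p = 0.0265 and adjusted p = 0.638 with an estimated correlation. The stromal lists pointed the other way. Myofibroblast genes were lower in 22 of 28 and higher in 2, with Prrx1 (-4.17), Cdh11 (-3.94, with 1 of its 3 probe sets of opposite sign) and Pdgfrb (-3.54), at adjusted p = 1.40e-05 and adjusted p = 0.0256 with an estimated correlation. Collagens and matrix were lower in 17 of 29 and higher in 4 (17 and 5 adjusted over the list alone), with Fbln5 (-4.36), Col11a1 (-4.10) and Vcan (-2.47), at adjusted p = 0.0265 and adjusted p = 0.381 with an estimated correlation. Basement membrane genes were lower in 12 of 19 and higher in 4 (12 and 5 adjusted over the list alone), with Col4a5 (-5.22), Nid2 (-3.81) and Lamc1 (-3.14), at adjusted p = 0.0450 and adjusted p = 0.191 with an estimated correlation. TGF-beta targets were lower in 15 of 20 and higher in 1 (16 and 1 adjusted over the list alone), with Ccn1 (-3.81), Id3 (-3.20) and Ltbp1 (-3.06), at adjusted p = 0.000287 and adjusted p = 0.0256 with an estimated correlation.

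The basement membrane list lost its call without epithelial array 2 (0.0512) or 3 (0.0521) or fibroblastic array 2 (0.0636) or 4 (0.0595), and cholesterol biosynthesis without fibroblastic array 2 (0.0539) or 4 (0.0728). Proliferation genes were not called (adjusted p = 0.0838), but were called higher in the tumours without fibroblastic array 3 (0.000241), without fibroblastic arrays 1 and 3 (7.24e-05) and with the lowest expressed genes left out (0.00348). Collagens and matrix lost their call at that last setting (0.210) and without fibroblastic arrays 1 and 3 (0.0692). Without fibroblastic arrays 2 and 4 calls ended for basement membrane (0.124), hypoxia (0.0525) and cholesterol biosynthesis (0.303). With the mean of the probe sets of a gene, basement membrane (0.0559) and cholesterol biosynthesis were not called, nor was the latter with tumours 1 and 4 left out (0.0714) or tumour 2 alone (0.239). Growth factor ligands (0.226), immediate early genes (0.385), the unfolded protein response (0.432, with a median of 0.10 and a mean of -0.03), growth factor receptors (0.609, with a median of 0.02 and a mean of -0.16) and proteases (0.990, with a median of -0.11 and a mean of 0.05) were not called.

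Genes placed on the same side of both lines set the tumours apart from either line as grown alone. Higher in the tumours than in both lines were 1701 genes, and 2547 were lower, 4248 in all. Cd74, Mmp12, RT1-Da, RT1-Bb, Lum, the complement genes Serping1 and C1qa, the antibody receptor Fcgr2b, Dcn and the liver products Alb and Fgg led the higher genes. Mmp12, for example, differed by 7.70 from the epithelial line and by 7.90 from the fibroblastic line. Ptgs2 (-3.97 and -3.78), the neurotrophin Bdnf (-2.81 and -3.94), Wasf2, Qrich1, Map2, the laminin chain Lamb2 and the transcription factor Gata3 were lower than in both. By list, 26 of 26 macrophage markers, 22 of 23 hepatocyte markers and 17 of 21 T, B and NK cell markers were above both lines. So were 14 of 19 endothelial markers, 12 of 24 interferon response genes and 6 of 10 erythrocyte and mast cell markers, while 5 of 19 basement membrane genes were below both. Both differences share the tumour arrays, and lists of these sizes drawn independently would overlap in 734 higher and 1582 lower genes. With the tumours split in pairs, 1 pair for each comparison, 935 to 1144 genes were higher and 1505 to 1665 lower. Median centring of the arrays gave 2568 higher and 1634 lower, and leaving out the lowest expressed genes 571 and 2375. A further 538 genes lay above the epithelial and below the fibroblastic line, and 511 the reverse. With tumour 2 as the only tumour, 941 genes lay on the same side of both lines, and 2366 with tumours 1 and 4 left out.

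**Figure D3:**
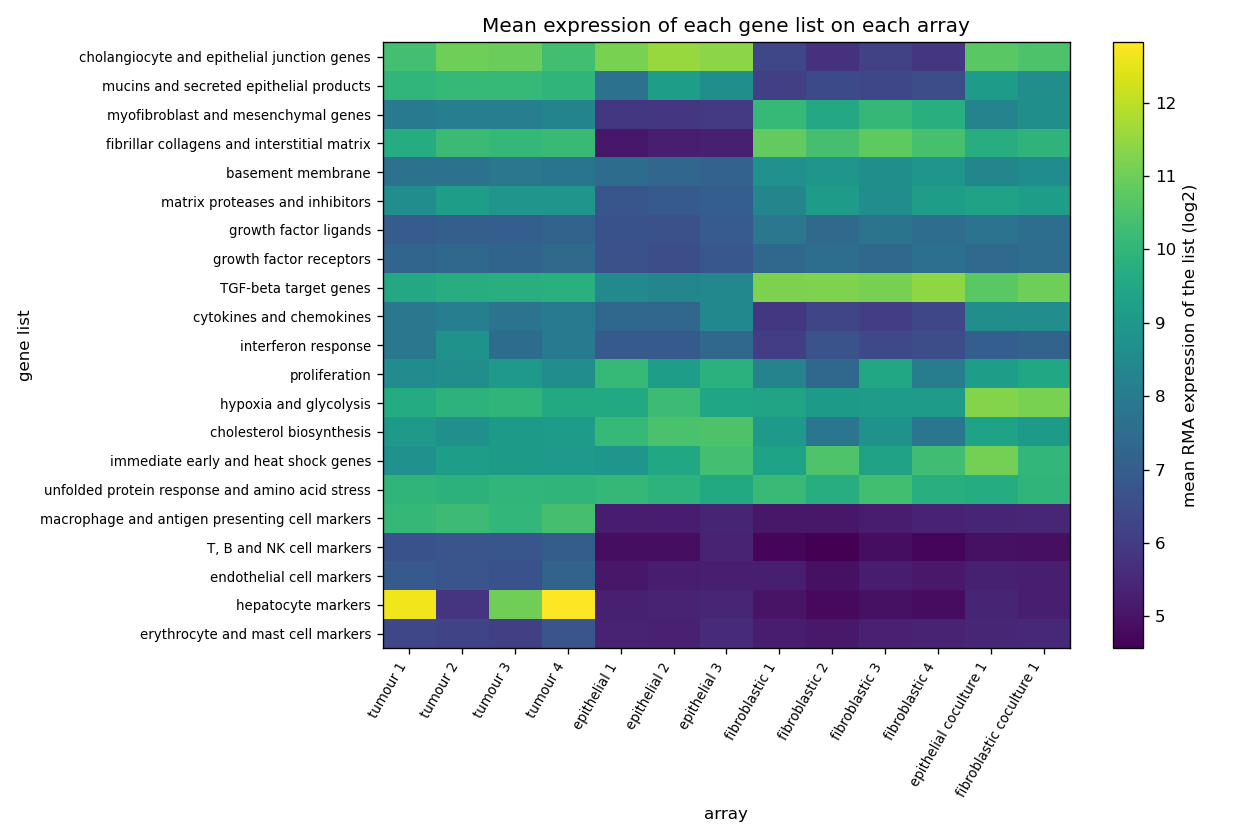
Mean RMA expression (log2, colour scale) of each of the 21 gene lists (vertical axis) on each of the 13 arrays (horizontal axis). The macrophage, lymphocyte and endothelial lists stand out in the 4 tumours, the hepatocyte list in tumours 1, 3 and 4 (12.6 in tumour 1, against 5.82 in tumour 2), and both co-culture arrays hold the epithelial and the matrix lists.

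The co-culture array labelled epithelial was compared with the epithelial line grown alone. As this array held genes of both lines, differences can follow from mixed RNA as well as from a response to contact. A comparison with a mixture of the lines is given below. Genes of the fibroblastic line filled the top of the list. Fn1 stood at 13.84 in the co-culture array and at 4.44 ± 0.28 (SD, n = 3) alone, a log2 difference of 9.40 (SE 0.25, adjusted p = 2.03e-06). It was followed by Col1a2 (9.10), Inhba (8.33), Serpine2 (8.20), Col5a2 (8.11), the tetraspanin Cd81 (8.00), the tenascin Tnn (7.94), the galectin Lgals1 (7.77), Grem1 (7.41) and the peroxidasin Pxdn (7.31). Lower in co-culture were the aldehyde dehydrogenase Aldh3a1 (-3.51), Clic3 (-3.43), Mbnl3 (-2.47) and the cytokine Il24 (-2.40). Smaller decreases were those of Padi1 (-2.38), Bmp3 (-2.33), Cavin2 (-2.32), the chemokine receptor Cxcr3 (-2.24), Serpinb2 (-2.24) and Psca (-2.22). Several genes of the identity set were not called. Krt19 differed by -0.57, Cdh1 by -0.79 (with 1 of its 2 probe sets of opposite sign), Krt7 by -0.91, Msln by -0.51, Muc1 by 0.78, Erbb2 by -0.68, Met by -0.63 and Mki67 by 0.29. Postn (6.96), Col1a1 (6.88), Vim (6.22) and Tnc (4.99) were higher, while Acta2 differed by 0.65 and was not called (adjusted p = 0.822). Of 14217 genes, 692 were higher and 337 lower, 1029 called. The number lower was unstable: 162 without epithelial array 1, 216 without epithelial array 2, 220 without fibroblastic array 3, 177 without fibroblastic array 4, 108 with only the groups compared and 820 in a single fit of all 13 arrays.

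Of the 21 lists, 12 were called, 10 higher and 2 lower in co-culture. Collagens and matrix were higher in 21 of 29 (22 higher and 1 lower adjusted over the list alone), with a median of 5.45 (adjusted p = 9.03e-27, and adjusted p = 0.00481 with an estimated correlation). Myofibroblast genes were higher in 15 of 28 (16 adjusted over the list alone), with Tpm2 (6.21) and the surface glycoprotein Thy1 in front, at adjusted p = 7.42e-14 and adjusted p = 0.00481 with an estimated correlation. Proteases and inhibitors were higher in 11 of 25 (15 adjusted over the list alone), with Timp3 (7.07) and Mmp2 (6.58), at adjusted p = 1.54e-11 and adjusted p = 0.0430 with an estimated correlation. TGF-beta targets were higher in 7 of 20 (8 adjusted over the list alone), with Ltbp2 (4.74), at adjusted p = 3.03e-08 and adjusted p = 0.0103 with an estimated correlation. Hypoxia and glycolysis genes were higher in 6 of 27 (9 adjusted over the list alone), with the glucose transporter Slc2a3 (5.78) and the mitophagy receptor Bnip3 (3.17), at adjusted p = 1.78e-09 and adjusted p = 0.154 with an estimated correlation. Basement membrane genes were higher in 6 of 19 (8 higher and 1 lower adjusted over the list alone), with Nid1 (6.51), Nid2 (4.06) and Col4a5 (2.49), at adjusted p = 7.14e-05 and adjusted p = 0.0622 with an estimated correlation. Growth factor ligands were higher in 4 of 31, with Vegfc (4.84) and Vegfa (3.20), at adjusted p = 0.00103 and adjusted p = 0.139 with an estimated correlation.

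Receptors were higher in the epithelial co-culture array in 5 of 25 and lower in 1 (6 and 1 adjusted over the list alone), with Axl (3.95), the collagen receptor Ddr2 (3.72) and Igf2r (3.48), at adjusted p = 0.0146 and adjusted p = 0.214 with an estimated correlation. Cytokines and chemokines were higher in 2 of 31, the monocyte chemokine Ccl2 (7.12) and Il6 (5.46), at adjusted p = 0.00103 and adjusted p = 0.428 with an estimated correlation. Immediate early and heat shock genes were higher in 2 of 22 (4 adjusted over the list alone), Klf2 (4.58) and Hspb1 (3.85), at adjusted p = 0.000396 and adjusted p = 0.349 with an estimated correlation. The cholangiocyte list was lower, with 1 of its 28 members called, the transcription factor Ehf (-1.62), a median of -0.70 and adjusted p = 0.00202, or adjusted p = 0.348 with an estimated correlation. Cholesterol biosynthesis was lower with 1 of 19 called, Mvk (-1.44), at adjusted p = 0.000670 and adjusted p = 0.591 with an estimated correlation. Without epithelial array 2 the mucin list was called higher (0.0371, against 0.156 with all arrays). The proliferation list was called lower without epithelial array 2 (0.0150) or fibroblastic array 2 (0.0433) or 3 (0.0171), against 0.0888, and without fibroblastic arrays 2 and 4 (0.0423) or 1 and 3 (0.0195). With 1 array left out at a time, calls ended for Aldh3a1 (epithelial array 1 or any fibroblastic array, adjusted p up to 0.0705) and Cavin2 (any epithelial array or fibroblastic array 1 or 2, up to 0.0989). They also ended for Psca (epithelial array 1 or 2 or fibroblastic array 2, 3 or 4, up to 0.104), Il24 (epithelial array 2, 0.0559) and Mbnl3 (epithelial array 1, 0.0521).

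The array labelled as fibroblastic cells from co-culture held genes of the epithelial line among those furthest higher. Here too, lower values of genes of the fibroblastic line can follow from mixed RNA. The highest difference was that of a gene low in both lines. Wfdc18, a secreted protein of the whey acidic protein family, stood at 13.59 against 4.12 ± 0.30 (SD, n = 4) alone, a log2 difference of 9.48 (SE 0.40, adjusted p = 1.20e-05). Krt19 (9.03), Krt18 (8.98), Tspan8 (8.48), Cdh1 (8.07), Epcam (7.95), the neutrophil chemokine Cxcl6 (7.81), the transglutaminase Tgm1 (7.65), Cd24 (7.41) and the protease Prss22 (7.37) followed. Lower were the gamma smooth muscle actin Actg2 (-6.13), the myosin light chain kinase Mylk (-5.15), the actin-binding Nexn (-5.63) and the guanylate cyclase subunit Gucy1b1 (-5.67). Mgp (-8.56), Abcc9 (-6.48), Col11a1 (-6.32), Gask1b (-5.88), Foxp2 (-5.76) and Abi3bp (-5.11) were lower too. Of 14217 genes, 679 were higher and 516 lower in co-culture, 1195 called.

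Msln (6.71), Krt7 (6.15, adjusted p = 0.0413) and Muc1 (3.58) were higher in the fibroblastic co-culture array and Postn (-3.79) lower. Fn1 differed by 0.03, Vim by 0.05, Col1a1 by -0.68, Tnc by -1.71, Acta2 by -1.88 (adjusted p = 0.392), Met by 0.65, Erbb2 by 1.05 (0.0609) and Mki67 by 1.68, and these were not called. Of the 21 lists 9 were called, 7 higher and 2 lower. Cholangiocyte genes were higher in 21 of 28 (25 adjusted over the list alone), with a median of 4.57 (adjusted p = 1.52e-30, and adjusted p = 0.0353 with an estimated correlation). Hypoxia and glycolysis genes were higher in 16 of 27 (20 adjusted over the list alone), with Egln3 (5.82), Ndrg1 (5.32) and the lactate transporter Slc16a3 (3.64), at adjusted p = 5.54e-13 and adjusted p = 0.235 with an estimated correlation. Cytokines and chemokines were higher in 12 of 31 and lower in 1 (15 and 1 adjusted over the list alone), with Cxcl2 (7.28) and Il33 (7.07), at adjusted p = 3.22e-08 and adjusted p = 0.235 with an estimated correlation. Mucins and secreted products were higher in 8 of 17, with Pigr (7.30) and Mal2 (7.03), at adjusted p = 8.63e-06 and adjusted p = 0.235 with an estimated correlation.

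Interferon response genes were higher in the fibroblastic co-culture array in 2 of 24, Psmb8 (3.00) and Usp18 (2.65), at adjusted p = 0.0238 and adjusted p = 0.499 with an estimated correlation. Proliferation (median 1.28) and cholesterol biosynthesis (median 0.78) were called higher as lists, with 0 members called by limma, at adjusted p = 7.48e-05 and 0.0335, and at adjusted p = 0.670 with an estimated correlation for both. The proliferation mean was 9.515 in this array, against 9.504 in fibroblastic array 3 and 7.333 to 8.254 in the others. The cholesterol mean was 9.058, against 9.033 and 8.815 in fibroblastic arrays 1 and 3 and 7.817 and 7.811 in arrays 2 and 4. Collagens and matrix were lower in 4 of 29 and higher in 2 (5 and 2 adjusted over the list alone), with Fbln5 (-3.47), at adjusted p = 0.00205 and adjusted p = 0.235 with an estimated correlation. Myofibroblast genes were lower in 6 of 28 and higher in 2, with Cdh11 (-4.13, with 1 of its 3 probe sets of opposite sign) and the myosin light chain Myl9 (-4.12), at adjusted p = 0.0360 and adjusted p = 0.235 with an estimated correlation. List calls ended without epithelial array 1 for myofibroblast genes (0.0553) and cholesterol biosynthesis (0.0581), and without fibroblastic array 2 (0.0815) or 4 (0.0990) for the latter. They also ended without fibroblastic array 1 for interferon response (0.0654). The latter was not called either with the lowest expressed genes left out (0.0630), where hepatocyte markers were (0.0112), or without fibroblastic arrays 1 and 3 (0.160). Myofibroblast genes lost their call with the mean of the probe sets of a gene (0.0849), as did cholesterol biosynthesis, also without fibroblastic arrays 2 and 4 (0.288). Gene calls ended for Krt7 without any epithelial array or fibroblastic array 2 (up to 0.0713), for Slc16a3 without epithelial array 2 or any fibroblastic array (up to 0.0696) and for Abcc9 without epithelial array 2 or 3 or fibroblastic array 4 (up to 0.0678). With the mean of the probe sets of a gene Col11a1 was not called (0.0528).

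The response to co-culture was tested for a difference between the lines. This contrast equals the difference between the co-culture arrays minus the difference between the lines grown alone. As the co-culture arrays were alike (r = 0.983 across genes), it largely restates the second with its sign turned. A different response of the lines is not shown by it. Genes of the fibroblastic line led on 1 side and genes of the epithelial line on the other, most of them having moved in 1 of the separate comparisons only. Postn (10.74, SE 0.32, adjusted p = 7.55e-06), Nrep (10.05), Col1a2 (9.78), Fn1 (9.37), Col5a2 (8.67), Mgp (8.64), Inhba (8.36), Nid1 (8.13), Grem1 (8.09) and Cpe (8.07) had the higher change under the epithelial label. Krt18 (-9.72), Krt19 (-9.60), Tgm1 (-9.01), Cdh1 (-8.86), Tspan8 (-8.64), Ocm (-8.48), Cd24 (-8.03), the platelet chemokine Ppbp (-7.99), Epcam (-7.93) and Il24 (-7.88) had the higher change under the fibroblastic label. The difference was positive (a higher change under the epithelial label) for 663 genes and negative for 535, 1198 of 14217. Vim (6.17), Tnc (6.70), Col1a1 (7.56), Msln (-7.22), Muc1 (-2.80) and Erbb2 (-1.73) were among them, while Acta2 (2.53, adjusted p = 0.416), Krt7 (-7.06, 0.0887), Met (-1.27, 0.216) and Mki67 (-1.39, 0.554) were not.

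Camera called 10 lists for this difference, 6 higher and 4 lower. They were the lists called between the lines grown alone, each with its direction turned. The median of collagens and matrix genes was 5.61, against -6.11 between the lines. Higher were collagens and matrix genes (adjusted p = 1.17e-24, and adjusted p = 0.00602 with an estimated correlation), myofibroblast genes with Tpm2 (7.51), Cdh11 (6.93) and Tagln (5.09) (1.05e-14, and adjusted p = 0.00594 with an estimated correlation) and TGF-beta targets (3.57e-07, and adjusted p = 0.0136 with an estimated correlation). Proteases with Serpine2 (7.70), Mmp2 (7.34) and Timp3 (5.84) (5.58e-07, and adjusted p = 0.103 with an estimated correlation), basement membrane genes with Col4a1 (5.39) and Col4a5 (5.35) (0.00295, and adjusted p = 0.135 with an estimated correlation) and ligands with Vegfc (5.30) and Fgf1 (3.44) (0.00528, and adjusted p = 0.182 with an estimated correlation) were higher too. Lower were the cholangiocyte genes (2.86e-25, and adjusted p = 0.0136 with an estimated correlation), mucins with Mal2 (-7.62) and Pigr (-5.85) (0.0149, and adjusted p = 0.634 with an estimated correlation), proliferation with Pcna (-1.90) (4.67e-05, and adjusted p = 0.648 with an estimated correlation) and cholesterol biosynthesis with Mvk (-1.93) (9.68e-05, and adjusted p = 0.640 with an estimated correlation). Cytokines (0.0677) were called without epithelial array 1 (0.0261) or 2 (0.0192) or fibroblastic array 4 (0.0456), and immediate early genes (0.0568) without fibroblastic array 1 (0.0279) or 3 (0.0338) or epithelial array 3 (0.00655). Cytokines were also called with the lowest expressed genes left out (0.00588), and immediate early genes without fibroblastic arrays 1 and 3 (0.00756), where mucins were not (0.0887). Interferon response was called without fibroblastic arrays 2 and 4 (0.0477). Calls ended for Erbb2 (without epithelial array 1 or 2 or fibroblastic array 1, 3 or 4, up to 0.0654), Muc1 (epithelial array 3 or any fibroblastic array, up to 0.0742), Tagln (any epithelial array or fibroblastic array 4, up to 0.0711) and Pcna (epithelial array 1 or 3 or fibroblastic array 4, up to 0.0531), and for Fgf1 with the mean of the probe sets of a gene (0.0655).

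With 1 array under each label, the co-culture arrays could be compared with each other only by description. They were alike, with a correlation across genes of 0.983, genes not being independent replicates. Of 886 genes called and at least 8-fold apart between the lines grown alone, the median absolute log2 difference was 4.29 between the lines and 0.42 between the co-culture arrays. Their difference correlated with that of the lines at r = 0.250 over all genes and 0.442 over these 886, with a slope of 0.0764. At least 2-fold apart were 352 genes, against 3646 between the lines. The array labelled epithelial was higher in the fatty acid carrier Fabp4 (6.21), the phospholipase Pla2g2a, the carbonic anhydrase Car1 (5.94), Reg3b (5.93), Agr2 (5.31) and Reg3g (5.29). It was lower in the chemokine Cxcl12 (-4.44), the neuropeptide Vip (-4.00), Wfdc21 (-3.38), the collagen-binding integrin Itga11 (-3.01) and Ccl7 (-2.82). These genes were named after their values were seen. Fabp4 and Car1 varied more widely among the epithelial arrays grown alone, at 5.78, 13.47 and 6.82 and at 4.36, 13.54 and 11.83. Reg3b (4.84 to 8.00) and Reg3g (4.34 to 7.15) varied less there than between the co-culture arrays. Among the lists, the median difference was 0.99 for immediate early and heat shock genes, 0.25 for cholangiocyte genes, -0.26 for proliferation, -0.30 for the unfolded protein response and -0.18 for myofibroblast genes. These medians lay at the percentiles 100, 100, 0.03, 0 and 2.43 of 10000 random lists matched on expression. Cholesterol biosynthesis lay at the percentile 100 too, hypoxia and glycolysis at 99.9, mucins at 99.5 and growth factor receptors at 2.08. With 1 array under each label, the percentiles measure the sampling of genes, not the spread between cultures. Collagens and matrix were lower in the array labelled epithelial (-0.19, percentile 2.3). Proteases (0.10, percentile 99.6) and growth factor ligands (0.15, percentile 99.9) were higher there, although higher in the fibroblastic line by calls lost with an estimated correlation (adjusted p = 0.154 and 0.231).

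**Figure D4:**
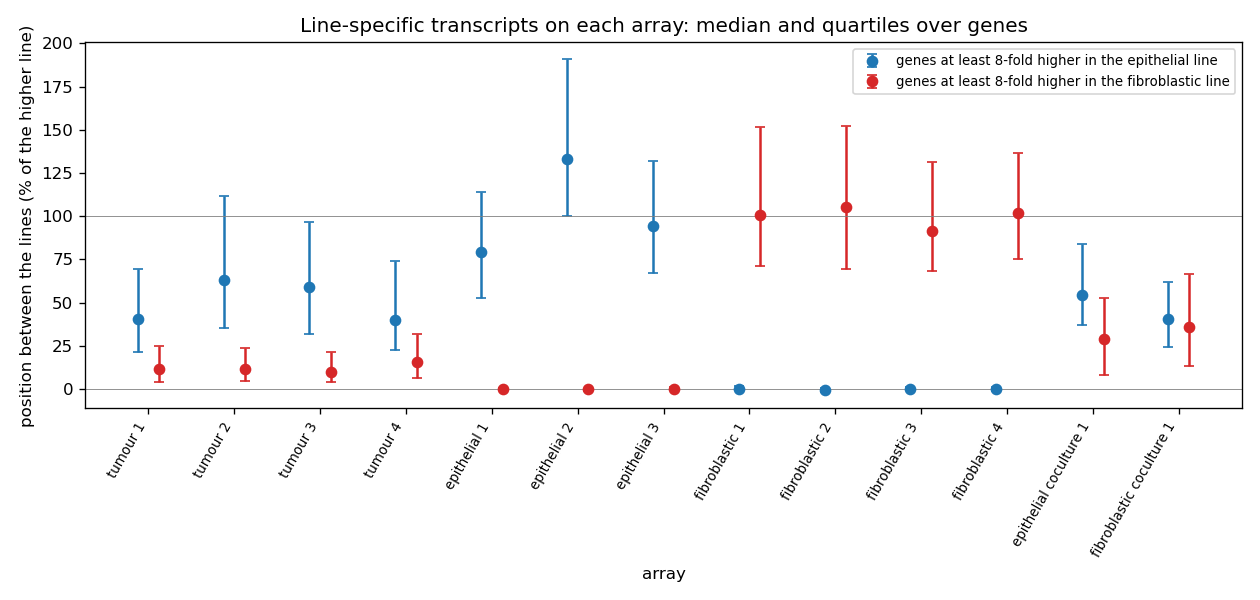
Position of each array (horizontal axis) between the lines grown alone, in percent of the level of the higher line on the linear scale (vertical axis); points are medians and bars quartiles over 355 genes at least 8-fold higher in the epithelial line (blue) and 531 in the fibroblastic line (red). The co-culture arrays lie at 54.6% and 28.8% (labelled epithelial) and at 40.5% and 36.0% (labelled fibroblastic), while arrays of a line grown alone lie near 0 for the genes of the other line.

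On the linear scale, the median of 531 genes of the fibroblastic line reached 28.8% of that line's level in the epithelial co-culture array (quartiles 7.99 to 53.0%) and 36.0% in the fibroblastic co-culture array (13.1 to 66.5%). The 355 genes of the epithelial line reached 54.6% (37.1 to 84.1%) and 40.5% (24.3 to 62.0%) in the same arrays. In the tumours the medians were 9.86 to 15.5% for fibroblastic and 40 to 62.8% for epithelial genes. Arrays grown alone, each placed against the others of its line, gave 79.1 to 133% for the epithelial and 91.6 to 105% for the fibroblastic line. The shares describe transcripts, not cells, and how the cells of a co-culture were separated before extraction is not given in the sources used here.

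Some genes left the range between the lines in both co-culture arrays, a comparison added after the data were seen. Above both lines in both arrays were 94 genes, by limma tests against each line. Wfdc18 stood at 11.62 and 13.59 in the epithelial and fibroblastic co-culture arrays, against means of 4.41 and 4.12 in the lines. The stromelysin Mmp3 (9.88 and 9.35), the lipid metabolism regulator Angptl8 (8.79 and 8.74) and Bnip3 (12.55 and 12.13) behaved alike. The secreted protein Olfm1, the collagen hydroxylase P4ha2, the glycolytic enzyme Gpi, Il6, the peroxide-generating oxidase Duox2, the cytokine Tnfsf9, the prostaglandin synthase Ptges and the adenosine receptor Adora2b were also above both. Below both were 12 genes, among them the malic enzyme Me1 and Taf1c, but 4 to 12 with 1 array left out. They were 4 without epithelial array 1 or fibroblastic array 1 or 4, and 5 without epithelial array 2 or fibroblastic array 3. Other choices raised the number below both to 37 (a single fit of all arrays), 27 (quantile normalization), 25 (without fibroblastic arrays 2 and 4) and 21 (without 1 and 3). The 94 above both became 49 with the lowest expressed genes left out and 144 without fibroblastic arrays 2 and 4. Of the hypoxia and glycolysis list 3 genes were above both (Bnip3, Gpi and P4ha2; Fisher's exact test, one-sided, adjusted p = 0.0153).

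**Figure D5:**
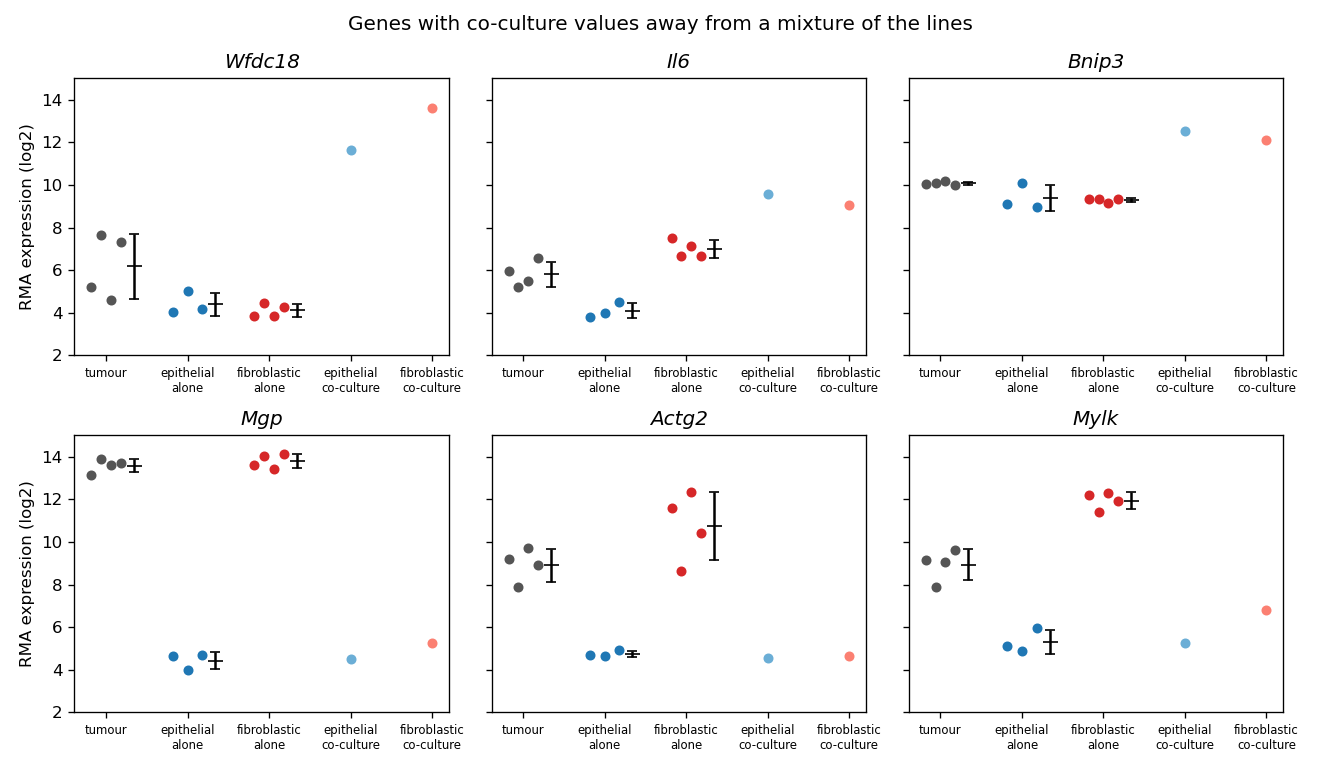
RMA expression (log2, vertical axis) of 6 genes in the 5 groups of arrays (horizontal axis); each point is an array and the bars beside the replicated groups give the mean and SD. Wfdc18, Il6 and Bnip3 lie above every array of both lines in the co-culture arrays, while Mgp, Actg2 and Mylk, high in the fibroblastic line, lie below every array of that line there, Mylk at 6.79 in the fibroblastic co-culture array being above the epithelial arrays.

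Measured against a mixture of the lines as grown alone, 378 genes were above and 583 below. The mixture used fibroblastic shares of 34.6% and 47.1% for the arrays labelled epithelial and fibroblastic. These are the median levels of fibroblastic genes (28.8% and 36.0%) divided by the sums of the fibroblastic and epithelial medians (83.35% and 76.55%). The mixture thus lies above the median measured level of the genes of both lines, which favours calls below it. How many of the 583 follow from this scaling was not tested. The number below was 381 without fibroblastic array 3 and 361 without fibroblastic array 4. Far below the mixture were Mgp (-7.62), Gask1b (-5.37), Abcc9 (-5.19), Col11a1 (-5.09), Actg2 (-4.89), Mylk (-4.63) and Nexn (-4.56), genes high in the fibroblastic line. Above it were the matrix protein Fbln2 (5.11), the proteoglycan Esm1 (4.85), Tnn (4.72) and Ccl2 (4.62). The hypoxia and glycolysis list had a median deviation of 1.47 (camera adjusted p = 2.34e-18), cytokines and chemokines 0.65 (7.57e-06) and proteases 0.46 (1.09e-05). Mucins (0.0130), collagens and matrix (0.0336), TGF-beta targets (0.0357) and immediate early genes (0.0364) were called too. These p-values use the preset correlation only, and the hypoxia and cytokine calls of both co-culture comparisons were lost with an estimated one. The tests against the mixture averaged the co-culture arrays and treated them as independent replicates, although their labels differ. Whether these arrays came from separate co-cultures is not given in the sources used here. If they did not, the p-values and the counts of 378 and 583 rest on a single co-culture and overstate the evidence.

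Whether the co-culture shift points toward the tumour was measured across genes. The shift of the epithelial co-culture array correlated with the difference between tumours and epithelial line at r = 0.508, against 0.365 in 1000 simulations with no effect and shared controls. The covariance was 0.621 against 0.0444. For the fibroblastic line r was 0.600, against 0.304 simulated, with a covariance of 0.874 against 0.0334, and 0.477 to 0.600 with the alone arrays split between the differences. The signs matched in 71.3% and 71.7% of genes. Both co-culture arrays hold genes of both lines, and a computed mixture of the lines as grown alone, added after the data were seen, gave r = 0.469 for the epithelial and 0.644 for the fibroblastic line. Mixing alone therefore gives values of this size. What deviated from the mixture correlated with the tumour difference at 0.224 and 0.158, but these values share the arrays grown alone and have no simulated counterpart, so a shift of the cells toward the tumour is left open. Genes are not independent replicates, so these values carry no p. Of the 94 genes above both lines in co-culture, 39 were also higher in the tumours than in both lines, where independent lists would share 11.2, and both comparisons use the same arrays of the lines grown alone.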

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

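The tests of explanations here were chosen after seeing the results. The first pattern is the presence of genes of the other line in both co-culture arrays. At least 2-fold above the mean of the line on the label were 79.1% of them in the epithelial co-culture array and 92.7% in the fibroblastic, against 2.45 to 5.63% in arrays grown alone, each set against the rest of its line. RNA of both cell types in each array could give the 79.1%, but this value describes the pattern itself and does not tell mixed RNA from an induction of these genes in unmixed cells. Swapped labels with unmixed cells would leave the genes of the line on the label near 0, whereas these genes reached 36.0% of their level in the fibroblastic co-culture array. A single mixing share does not account for all genes: the lower quartile of fibroblastic genes in the epithelial co-culture array was 7.99%, Cxcl12 stood at 4.88 and 9.32 in the arrays labelled epithelial and fibroblastic, and Mgp stood near the level of the epithelial line in both. A difference in response to co-culture was called for 1198 genes and 10 lists. As the co-culture arrays were alike (r = 0.983 across genes), these calls largely restate the difference between the lines with its sign turned. They do not show that the lines respond differently.

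The second pattern is the low level of hepatocyte transcripts in tumour 2. Of the hepatocyte markers, 22 of 23 were at least 2-fold lower in tumour 2 than in each other tumour, the exception being Cyp3a9 with a difference of 0.25. The hepatocyte list shares no gene with the other lists, and its median in tumour 2 was lower than the mean of the other tumours by a log2 difference of -6.80. RNA degradation in tumour 2 was not seen, as its difference between the 3' and 5' actin probe sets was 0.693, against 0.606 to 0.752 over the tumours. Liver tissue in 3 of the 4 tumour samples could give this, but the 22 of 23 restate the pattern, and the source of these transcripts is left open.

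Values that stood apart from their group were sought over 392 sets of values with Dixon's ratio at a level met by chance in 1 of 20. The level was met by 11, fewer than the 19.6 expected by chance, the sets not being independent of each other. In tumour 2 these were Alb (7.50 against 13.94 to 14.51, ratio 0.919), Fga (0.839), Fgg (0.864), Col11a1 (7.81 against 6.17 to 6.41, 0.853) and Col4a1 (9.17 against 9.94 or more, 0.925). In tumour 3 they were the mean of the proliferation list (above a range of 8.56 to 8.63, 0.839), Cxcl2 (6.25 against 7.39 to 7.54, 0.882) and Sdf2l1 (9.90 against 10.15 to 10.20, 0.834), and in tumour 1 Slc2a3 (5.83 against 6.38 to 6.47, 0.861). In fibroblastic array 4 they were Ehf (4.43 against 5.00 to 5.11, 0.836) and Fn1 (13.58 against 13.73 to 13.76, 0.841).

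Probe sets without a gene symbol differed between the lines too. Of 9780 such probe sets 2188 were called, 963 higher and 1225 lower in the epithelial line, and what they measure was not analysed here.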

How the results depend on the processing

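Of 167 values from alternatives other than leaving out an array, 128 stayed within 1.5 times the value given, or within its spread, and of 182 values with an array left out 170 did. Between the lines 5324 genes were called, 9567 probe sets when each was tested on its own, 3310 at 2-fold and 3391 at adjusted p under 0.01. Tumours against the epithelial line gave 13988 probe sets, 3465 genes at 2-fold, 4878 at adjusted p under 0.01, 4549 with tumours 1 and 4 left out and 1958 with tumour 2 as the only tumour. Tumours against the fibroblastic line gave 17443, 4343 at 2-fold and 3912 with tumour 2 alone. For genes on the same side of both lines the values were 8242, 1492 at 2-fold, 2525 at adjusted p under 0.01, 2366 with tumours 1 and 4 left out and 941 with tumour 2 alone. Counts of probe sets exceed counts of genes because a gene can have several; stricter limits lower counts by construction. For the other changes the cause was not tested.

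In the epithelial co-culture 1743 genes were called by a single fit of all 13 arrays and 453 at adjusted p under 0.01. In the fibroblastic co-culture the values were 1924 by probe set, 532 at adjusted p under 0.01 and 1839 with fibroblastic arrays 1 and 3 left out, and the difference in response gave 632 at adjusted p under 0.01. With an estimated correlation the lists called were 4 between the lines, 6 and 4 for tumours against the epithelial and fibroblastic line, 4 and 1 for the epithelial and fibroblastic co-culture, and 4 for the difference in response. The shift toward the tumour was 0.592 and 0.661 for the epithelial and fibroblastic line with the lowest expressed genes left out. Genes above both lines in co-culture numbered 49 with those genes left out and 144 without fibroblastic arrays 2 and 4. Genes below both numbered 37 by a single fit, 27 after quantile normalization, 25 without fibroblastic arrays 2 and 4 and 21 without 1 and 3. Above the mixture were 577 without fibroblastic arrays 2 and 4, and below it 917 without these and 890 without 1 and 3.

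With 1 array left out the calls ranged from 4431 to 4985 between the lines, 5991 to 7569 for tumours against the epithelial line, 7717 to 8703 against the fibroblastic line and 3359 to 4116 against both. In co-culture they ranged from 740 to 950 (epithelial), 877 to 1095 (fibroblastic) and 989 to 1190 (difference in response). The shift toward the tumour ranged from 0.476 to 0.539 (epithelial) and 0.566 to 0.620 (fibroblastic). Above both lines were 76 to 90 genes and below both 4 to 12; above the mixture were 298 to 344 and below it 361 to 514. The share of epithelial genes ranged from 50.3 to 58.7% in the epithelial and 36.3 to 46.9% in the fibroblastic co-culture array.

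With the replicate number as a replicate block, 4252 genes were called between the lines, 6638 and 8405 for tumours against the epithelial and fibroblastic line, and 3834 against both. Correlations of deviations from the group mean between arrays of the same number ran from -0.15 to 0.14, so the numbers do not pair the arrays.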

Other observations

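The tests of genes above both lines were chosen after seeing the result, and the splits of the arrays were planned before. Genes above both lines in both co-culture arrays numbered 94, against 0 as the highest of 20 simulated mixtures. A mixture of the measured means lies between its parts in any share, so the 0 tests only the noise added to each gene. The simulations used the estimated shares and no shift between cultures. Mixing the lines as measured here therefore does not account for the 94 genes. A difference between the co-cultured cells and those grown alone for other reasons was not simulated. Of the 94 genes, 89 were called again after quantile normalization and 89 with each array centred on its median. The deposited values were already normalized by RMA, with array medians from 6.141 to 6.245, so both changes are small. An effect of the original normalization is left open by them. A batch or day of culture shared by the co-culture arrays cannot be told from an effect of co-culture, as the labels name no batch. The mean of the hypoxia and glycolysis list in the lower co-culture array exceeded the highest array grown alone by 0.961, and either would give that. The values are consistent with a response of at least 1 cell type, which the 94 genes do not assign to a line.

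Arrays assigned to groups in other ways show whether chance alone could give as many calls. For genes between the lines 1 of 35 splits, the real one, was as large (5324, against 0 at most otherwise). Chance assignment of independent arrays would give this in 1 of 35. Other splits mix the lines, which widens the spread within groups and lowers their counts. Whether the arrays are independent is not known, and the fibroblastic arrays formed pairs. For gene lists between the lines 14 of 35 splits gave as many, up to 13 against 10, so chance was not excluded for the number of lists. For tumours against the epithelial line 1 of 35 splits was as large, with 7407 genes against 2997 and 16 lists against 15. For tumours against the fibroblastic line it was 1 of 35 too, with 8652 genes against 2 and 15 lists against 14. For tumours against both lines 1 of 100 splits was as large, with 4248 genes against 3892. Other splits with many calls point to structure among the arrays.

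The fibroblastic arrays formed pairs: arrays 1 and 3 correlated at 0.987 and arrays 2 and 4 at 0.990, against 0.947 to 0.961 for the other pairs. The difference between the 3' and 5' actin probe sets, a sign of RNA quality, was higher in arrays 2 and 4 (2.65 and 2.01) than in arrays 1 and 3 (1.72 and 1.05, the latter the lowest of the group). Acta2 stood at 12.1, 9.29, 12.0 and 10.3 in fibroblastic arrays 1 to 4, Krt7 at 8.99, 5.40, 8.23 and 4.65, and the contractile protein gene Cnn1 at 11.9, 8.61, 11.9 and 9.80. Epithelial array 1 held Agr2 at 6.83, against 11.65 and 12.10 in arrays 2 and 3, and the co-culture arrays held it at 10.59 (epithelial) and 5.28 (fibroblastic). The difference between the co-culture arrays correlated across genes with the deviation of epithelial array 1 from its group at -0.501 and with that of epithelial array 2 at 0.343, genes not being independent replicates. In tumour 2 the interferon list had a median difference of 1.20 from the mean of the other tumours and 19 of 24 genes were highest there. The cause of these values was not tested.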
